A study of Mus musculus with 12 samples.

How the data were processed

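Ultralow-input RNA sequencing (Smart-seq2) had been carried out on P14 CD8 T cells sorted 37 to 38 days after infection with LCMV Armstrong, with 4 libraries each of prostate TRM, spleen TEM and spleen TCM. Per the labels, 3 mice were pooled for each replicate, 5000 live P14 cells were sorted, and 1000 were sorted again into lysis buffer. Prostate cells were gated on the population not stained by the intravenous antibody, and libraries were amplified for 18 cycles and read as pairs of 25 bp. The spleen was disrupted mechanically, and the prostate was shaken with collagenase for 30 min at 37 °C and its lymphocytes taken from a Percoll gradient. The gate that parted TEM from TCM and the sex of the mice are not given in the sources used here. The labels do not say which libraries share mice, so the p-values may measure technical spread rather than spread between animals.

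Per the submitters' processing notes, reads were aligned with STAR 2.5.4a to GRCm38 (mm10), counted with featureCounts of the Subread package and normalised with DESeq2, and the annotation release is not given in the sources used here. The deposited values are a signal: normalised read counts to which the authors added 1. The table holds 55011 gene symbols, and 100% of its values lie within 0.01 reads of a whole number of reads after 1 is subtracted and the value is divided by that of 1 read. A read was worth between 0.697 and 1.42 normalised counts. Levels in the text are the deposited values minus 1. Libraries held 2872067 to 5080924 gene-assigned reads, and 12091 genes had no read in any library. The library kit does not keep the strand, so overlapping antisense genes cannot be separated, and reads of near-identical genes can be assigned wrongly. The reads carry no molecular tags, so that floors cover counting error of amplified reads alone. A fold against a group without reads was taken against a floor of 3 reads over the group, a mean normalised count of 0.894 in TRM, 0.649 in TEM and 0.722 in TCM. Gene positions come from GENCODE M21 on GRCm38, in which 52830 of the symbols match 1 gene.

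Genes were tested when their deposited value was at least 10 in at least 4 of the 12 libraries, which left 12177. A linear model with the 3 groups was fitted to log2 of the deposited value plus 1 (the normalised count plus 2) in limma 3.58.1 (R 4.3.3), with empirical Bayes variances that follow an intensity trend, and p-values were adjusted by the method of Benjamini and Hochberg. A gene was called at an adjusted p under 0.05. Fold changes on this scale understate the change of genes with low counts. The 3 comparisons were TRM against TEM, TRM against TCM and TEM against TCM. Groups, comparisons, filter, test, gene lists, the rule for named genes and most alternative settings were set before the data were examined.

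There were 35 fixed gene lists, with 946 members found in the table and 3 symbols not found. Lists with at least 5 tested members were tested with camera in limma at the preset correlation of 0.01, and p-values were adjusted over the lists and comparisons together. The same test with a correlation estimated for each list is given beside it. Counts of called members are given over all genes and adjusted over the list alone.

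Named genes follow a rule. For each comparison they are the 8 genes with the largest change in each direction among those called, with a mean deposited value of at least 100 in the higher group and with groups that do not overlap, leaving out predicted genes and receptor segments. To these are added up to 3 members of each list with the smallest adjusted p, and a fixed set of reference genes. Genes named as the members that moved against their list, as all the called members of a list, or for their level in the third group of libraries were chosen after their values were seen. Some genes that the rule names are not reported here.

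The overlap of the TRM comparisons was set against the product of the list lengths over the number of genes and against comparisons with the TRM libraries split. The correlation of their fold changes was also set against 50 simulations of groups without differences (seed 21). The position of TRM between TEM and TCM is the median over genes called between TEM and TCM. Libraries were checked for duplicates by comparing their recovered reads. On simulated data with the spread of these groups, the test of TRM against TEM recovered 55.0% of 2-fold and 84.2% of 4-fold changes with 5 false calls of 140, and that of TEM against TCM recovered 57.6% and 83.5% with 9 false calls of 147. In the simulation of TRM against TEM, 0 of 40 lists without change were called. Genes were drawn independently there, so this says nothing of lists whose genes vary together. In the real data the estimated correlation was 0.399 for the macrophage and dendritic cell markers.

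A library was singled out in its group of 4 when its gap to the nearest other exceeded 0.829 of the range (Dixon's test). The alternatives changed the pseudocount, the filter, the scaling, the groups in the fit, blocks for the label's numbers, library weights, the variance prior, the threshold, the list test and the libraries used. Voom on the recovered reads, log2 without a further pseudocount, and fits without 2 TRM or 2 spleen libraries or on 1 set were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, checks and figures.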

Results

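P14 cells are CD8 T cells that carry a transgenic T cell receptor for a peptide of the lymphocytic choriomeningitis virus (LCMV) glycoprotein, so that virus-specific memory cells can be followed after infection. They were sorted 37 to 38 days after infection of mice with the Armstrong strain, which causes an acute infection that is cleared. The 12 libraries formed 3 groups of 4: tissue-resident memory cells (TRM) of the prostate, taken from the gate shielded from an intravenous antibody, and effector memory (TEM) and central memory (TCM) cells of the spleen. Each library pooled cells of 3 mice, and 1000 cells were re-sorted from a first sort of 5000. Gene-assigned reads came to between 2872067 and 4056881 per TRM library, between 3793210 and 4611440 per TEM library and between 3198132 and 5080924 per TCM library. Between 20332 and 25074 genes had at least 1 read in a library. Levels below are normalised read counts, given as mean ± SD over the 4 libraries of a group.

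The prostate cells stood apart from both spleen groups in the whole transcriptome. The first principal component held 47.3% of the variance over the 12177 genes tested and separated the 4 TRM libraries from the 8 spleen libraries. The second held 10.6% and set library TCM 1-1 apart, and the third, with 8.31%, set library TEM 1-1 apart from the other spleen libraries. The third also parted the spleen groups, with scores of 2.99 to 24.1 in TCM and -51.8 to -2.60 in TEM. TCM 1-1 also had the highest share of mitochondrial reads of all 12 libraries, 5.80%, against 1.22% to 2.11% in the other 11.

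**Figure D1:**
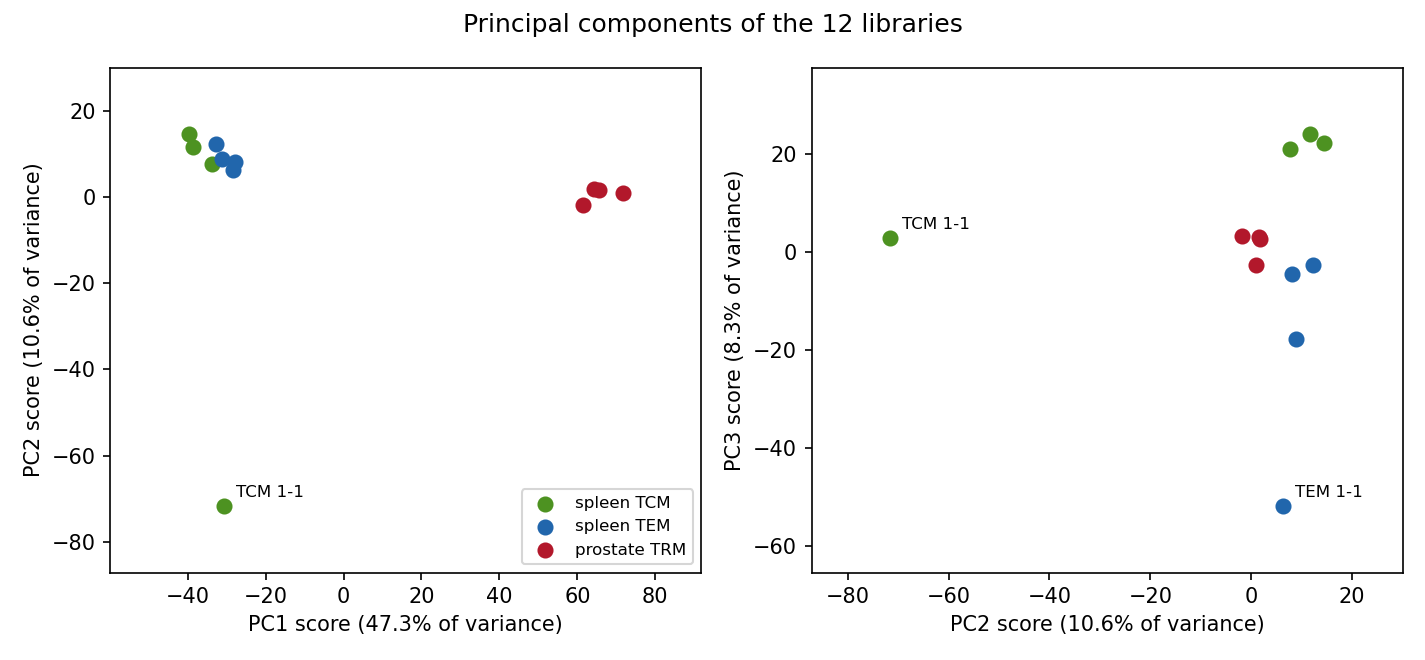
Each point is 1 library placed by its scores on principal components 1 and 2 (left) and 2 and 3 (right) of the log2 values of 12177 genes, coloured by group. The TRM libraries lie at 1 end of component 1, which holds 47.3% of the variance, and the spleen libraries TCM 1-1 and TEM 1-1 stand apart on components 2 and 3.

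The first comparison asked how resident cells of the prostate differed from circulating effector memory cells. Genes that mark residency were higher in TRM. Itgae, which encodes the integrin chain CD103 that binds E-cadherin (GRCm38 chromosome 11, 73090583 to 73147446), stood at 2324 ± 395 in TRM and 43.8 ± 20.01 in TEM, a log2 fold change of 5.74 ± 0.28 (SE; limma adjusted p = 6.94e-12). Cd69 (chromosome 6, 129267325 to 129275436), whose product holds the egress receptor S1PR1 inside the cell, stood at 3239.5 ± 216 against 376 ± 50.5 (log2 fold change 3.11 ± 0.11, adjusted p = 8.77e-14). Itga1, the collagen-binding integrin chain CD49a, rose by a log2 fold change of 1.78. Genes of recirculation went the other way. S1pr1 (chromosome 3, 115710433 to 115715072), the receptor that guides lymphocytes out of tissue, stood at 421 ± 89.7 in TRM and 2178 ± 145 in TEM (log2 fold change -2.39 ± 0.12, adjusted p = 8.54e-12). S1pr5 (chromosome 9, 21242912 to 21248443) stood at 21.3 ± 3.74 and 1099 ± 456 (log2 fold change -5.49 ± 0.28), and Klf2 (chromosome 8, 72319033 to 72321656), the transcription factor that drives S1pr1, at 60.4 ± 12.8 and 193 ± 15.5.

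Counted by list, 36 of 39 tested tissue residency genes rose in TRM against TEM and 0 fell, 38 adjusted over the list alone, with a median log2 fold change of 3.15 (camera adjusted p = 1.28e-36, and adjusted p = 1.10e-04 with an estimated correlation). Of 34 circulation and tissue egress genes 25 fell and 0 rose, also 25 adjusted over the list alone, with a median of -1.08 (camera adjusted p = 1.47e-17, and adjusted p = 5.60e-04 with an estimated correlation). Among 21 residency-linked transcription factors 14 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 9.22e-08, and adjusted p = 0.0243 with an estimated correlation). They included the orphan nuclear receptors Nr4a1 (chromosome 15, 101254269 to 101274795; 9361 ± 1198 in TRM, 17.3 ± 6.97 in TEM), Nr4a2 and Nr4a3, with log2 fold changes of 8.98, 9.21 and 7.77. Nr4a1 is also a member of the tissue residency and immediate early lists, and 22 of the 40 tissue residency genes are in another list. Only the prostate was digested with collagenase. An effect of digestion thus cannot be told apart from residency for any gene, against TEM or against TCM. This includes the residency genes that are also immediate early genes. Of the residency-linked factors Batf, Gata3 and Id2 fell. Zfp683, which encodes Hobit, stood at 181 ± 48.6 against 101 ± 15.5 (adjusted p = 0.0168), a call that was lost without TRM 1-2 (adjusted p = 0.0687), TRM 2-1 (0.0552) or TEM 1-2 (0.0551). Of 17 circulating memory transcription factors 6 fell, among them Tcf7, Lef1 and Klf3 with log2 fold changes of -1.19, -1.06 and -1.43, and 3 rose (7 and 3 adjusted over the list alone). The camera adjusted p of that list was 0.0128, adjusted p = 0.0634 with an estimated correlation, and 0.885 without the genes of other lists. Of 22 genes of the TGF-beta pathway and response 13 rose and 2 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 8.69e-06, and adjusted p = 0.00485 with an estimated correlation). Itgae, Tgif1 and Skil were among them, and the last 2 encode corepressors of SMAD proteins (log2 fold changes 3.15 and 2.43).

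**Figure D2:**
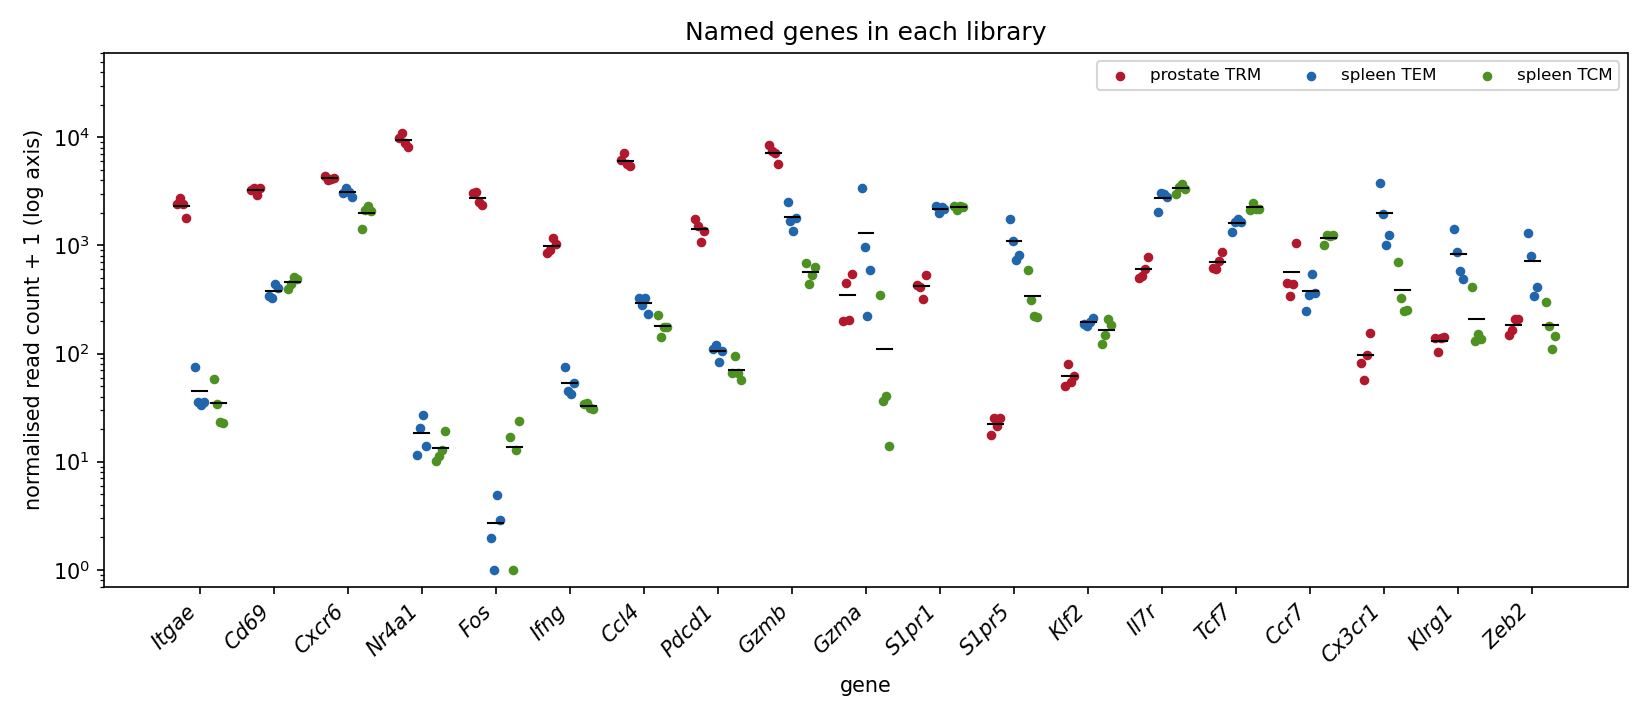
Normalised read counts plus 1, on a log axis, of 19 named genes in each of the 12 libraries; a point is 1 library and a bar the mean of the 4 libraries of a group. Itgae, Cd69, Nr4a1, Fos, Ifng, Ccl4 and Pdcd1 lie higher in the 4 TRM libraries than in the 8 spleen libraries, and S1pr1, S1pr5, Klf2, Il7r and Tcf7 lie lower.

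Effector transcripts were split between TRM and TEM. Gzmb, which encodes granzyme B, stood at 7162 ± 1174 in TRM and 1842 ± 497 in TEM (log2 fold change 1.98 ± 0.16, limma adjusted p = 2.23e-08). Fasl stood at 2447 ± 233 and 422 ± 37.1, and Serpinb9, the granzyme B inhibitor, at 2208 ± 396 and 459.6 ± 47.8. Gzma did not pass the test (349 ± 173 and 1290.0 ± 1429.6). The cytokine genes Ifng and Tnf and the chemokine gene Ccl4 rose by log2 fold changes of 4.20, 4.25 and 4.38, from 52.9 ± 15.2, 79.7 ± 25.1 and 289.9 ± 43.9 in TEM to 990.1 ± 137, 1505 ± 106 and 6055 ± 759 in TRM, whereas Ccl5 fell by 1.37 on the log2 scale. Cx3cr1, the fractalkine receptor of circulating effector cells (96.6 ± 41.9 in TRM, 1991 ± 1242 in TEM), and Klrg1, a receptor of terminally differentiated cells (129.8 ± 18.4 and 836 ± 410.5), also fell. Of 22 cytotoxic granule and killing genes 10 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00284, and adjusted p = 0.154 with an estimated correlation). Of 18 cytokine and chemokine genes 8 rose and 3 fell, 8 and 5 adjusted over the list alone (camera adjusted p = 0.00296, adjusted p = 0.0658 with an estimated correlation, and 0.0543 without the genes of other lists). Of 33 effector memory and terminal effector genes 16 fell and 10 rose, 18 and 11 adjusted over the list alone, with a camera adjusted p of 0.0291 for a fall, and adjusted p = 0.562 with an estimated correlation. That last call was lost without TEM 1-1 (adjusted p = 0.0923), and without the genes it shares with other lists the direction turned (adjusted p = 0.328).

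Inhibitory and costimulatory receptors and immediate early genes rose in TRM against TEM. Of 25 inhibitory and costimulatory receptors 16 rose and only Klrg1 fell, 19 and 2 adjusted over the list alone (camera adjusted p = 2.12e-11, and adjusted p = 5.60e-04 with an estimated correlation). Pdcd1, which encodes PD-1, stood at 1419 ± 295 in TRM and 104 ± 15.5 in TEM (log2 fold change 3.73 ± 0.18, limma adjusted p = 6.39e-12), and Icos and Tigit rose by 3.29 and 2.95 on the log2 scale. Of 34 immediate early genes 31 rose and only Ier3 fell, 32 and 1 adjusted over the list alone, with a median log2 fold change of 3.53 (camera adjusted p = 8.98e-33, and adjusted p = 5.60e-04 with an estimated correlation). Fos stood at 2765 ± 397 in TRM and 1.69 ± 1.69 in TEM (log2 fold change 9.65 ± 0.55, adjusted p = 6.36e-11). Dusp1, a phosphatase of MAP kinases, rose by 5.70, and Tnfaip3, which encodes the NF-kB inhibitor A20, by 4.74 on the log2 scale. Of 21 heat shock and chaperone genes 11 rose and 0 fell, the same numbers adjusted over the list alone, with a median of 0.46 (camera adjusted p = 5.93e-05, and adjusted p = 0.0296 with an estimated correlation). Hspa5 and Dnaja1 rose by 0.94 and 1.14. Hspa1a, whose reads cannot be told surely from those of its near-identical neighbour Hspa1b, stood at 59.6 ± 20.9 in TRM and had 0 reads in the 4 TEM libraries, which makes it at least 91.8-fold higher against a floor of 3 reads over the group. With Hspa1a at that bound the list's median was 0.46 as well. The prostate, and not the spleen, was digested with collagenase for 30 min at 37 °C, per the labels' protocols. Of 28 NF-kB pathway and target genes 12 rose and 5 fell, 12 and 6 adjusted over the list alone (camera adjusted p = 7.77e-04, adjusted p = 0.0981 with an estimated correlation, and 0.125 without the genes of other lists). Of 20 steroid hormone receptors and steroid-responsive genes 9 rose and 3 fell, 9 and 4 adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.0634 with an estimated correlation, and 0.352 without the genes of other lists). Per1, a clock gene, had the smallest adjusted p of that list, with a log2 fold change of 3.34.

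Cholesterol synthesis genes rose in TRM against TEM, and the calls of the glycolysis and proliferation lists were lost with an estimated correlation. Of 25 cholesterol synthesis genes 15 rose and only Ggps1 fell, 16 and 1 adjusted over the list alone (camera adjusted p = 4.93e-06, and adjusted p = 0.0193 with an estimated correlation). Insig1, a sterol sensor, stood at 426 ± 59.1 in TRM and 62.4 ± 10.5 in TEM (log2 fold change 2.74 ± 0.19, limma adjusted p = 1.76e-09), and Cyp51, which demethylates lanosterol, at 354 ± 66.96 and 79.4 ± 20.9. Of 22 glycolysis genes 9 rose and 0 fell, 11 and 0 adjusted over the list alone (camera adjusted p = 3.98e-04, and adjusted p = 0.129 with an estimated correlation), with Gapdh higher by 0.83. Of 35 proliferation genes 26 rose and only Racgap1 fell, 30 and 1 adjusted over the list alone (camera adjusted p = 1.13e-10, and adjusted p = 0.0734 with an estimated correlation). Top2a, a topoisomerase of dividing cells, stood at 333 ± 82.8 and 63.9 ± 20.1, and Bub1, a spindle checkpoint kinase, at 33.2 ± 16.5 and 1.37 ± 1.23.

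Transcripts of other cell types were measured in the same libraries. Of 20 macrophage and dendritic cell markers 15 rose in TRM against TEM and only Itgax fell, 16 and 1 adjusted over the list alone (camera adjusted p = 2.33e-07, and adjusted p = 0.149 with an estimated correlation). Apoe stood at 707 ± 420.3 in TRM and 22.3 ± 8.20 in TEM, and H2-Ab1 and H2-Eb1, which encode MHC class II chains, at 439 ± 348 and 228 ± 156 against 17.1 ± 11.9 and 13.6 ± 3.68. The sum of the C1q, Lyz2 and Csf1r transcripts, all made by macrophages, lay between 175 and 903 in the TRM libraries, between 14.1 and 54.9 in TEM, and between 2.28 and 20.8 in TCM apart from TCM 1-1 at 359. Of 5 CD4 T cell markers 2 rose, also 2 adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.125 with an estimated correlation). That call was also lost without TRM 2-1 and TRM 2-2 (camera adjusted p = 0.0718). The 2 markers were Cd40lg and Ctla4, both also made by activated CD8 T cells, and Ctla4 stood at 502 ± 112 and 27.8 ± 9.96. Of 11 B cell markers 1 rose and 3 fell, 1 and 4 adjusted over the list alone (camera adjusted p = 0.169). Of 8 NK cell markers 2 rose and 2 fell, 3 and 2 adjusted over the list alone (camera adjusted p = 0.746). TRM 2-2 held 19598.2 normalised reads of Ighm, Igkc and Jchain against 258 to 1298 in the other TRM libraries. TRM 2-1 held 1643.9 of prostate epithelium markers against 389.9 to 442 in the other TRM libraries. The spleen libraries held 187 to 281 (TEM) and 247 to 384 (TCM) of the same markers. Tgm4, a prostate transglutaminase, stood at 145 ± 243 in TRM and 1.88 ± 1.43 in TEM, with 509.7 in TRM 2-1. The lists of prostate epithelium, seminal vesicle, fibroblast and smooth muscle, endothelial, neutrophil, and red blood cell and platelet markers had fewer than 5 tested genes and were not tested as lists. Of their sums, that of endothelial markers lay between 416 and 628 in TRM and between 74.7 and 139.8 in the spleen libraries. That of fibroblast and smooth muscle markers lay between 1795 and 2071 against 1039 to 1411, and that of red blood cell and platelet markers between 55.6 and 224.5 against 14.0 to 48.6. Few members passed the filter: 1 of 16 endothelial, 2 of 27 fibroblast and smooth muscle, and 3 of 12 red blood cell and platelet markers. The endothelial and fibroblast members that passed were called higher in TRM in both comparisons. Of the red blood cell and platelet members 1 rose against TEM, and against TCM 1 rose and 1 fell. These sums may thus follow few genes and do not show RNA of the cell types.

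**Figure D3:**
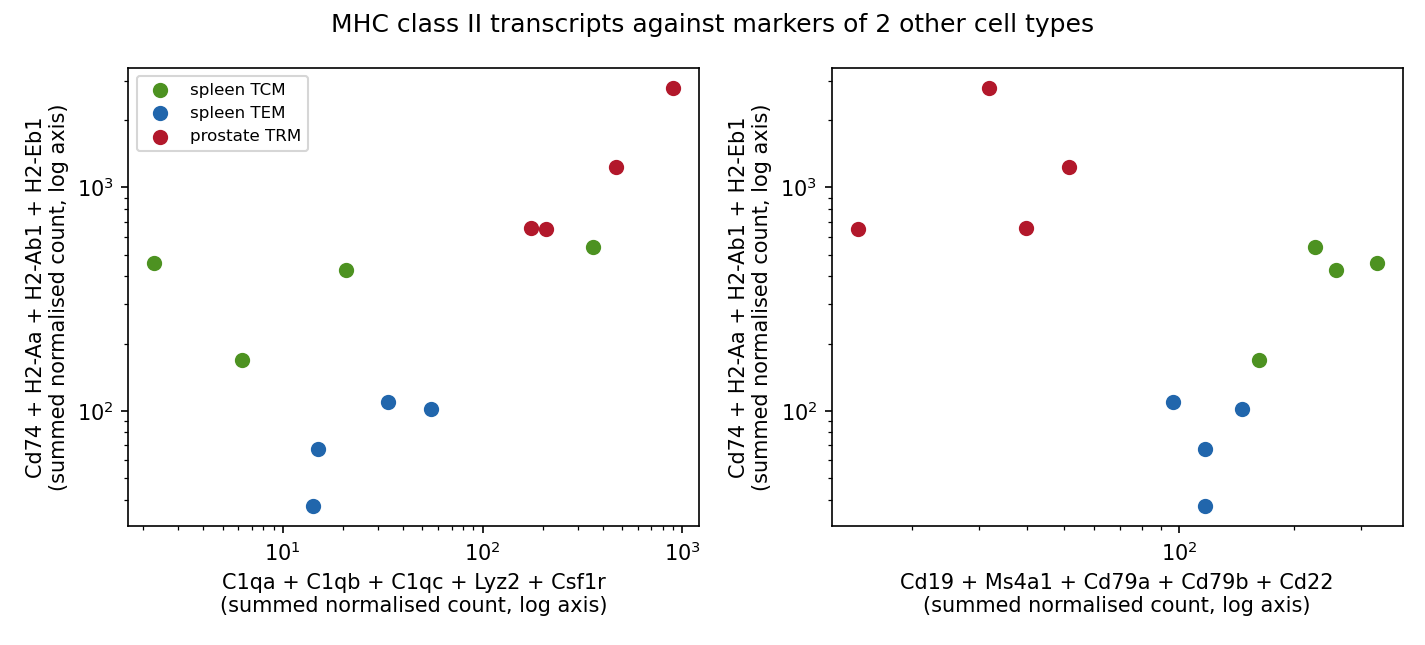
Sum of MHC class II transcripts against the sum of C1q, Lyz2 and Csf1r transcripts (left) and of B cell transcripts (right) in each of the 12 libraries, in normalised read counts on log axes, coloured by group. In the TRM libraries the ratio of these sums (left) lies between 2.64 and 3.75, and 3 TCM libraries lie at ratios from 20.6 to 201.5.

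In all, 3200 of 12177 genes differed between TRM and TEM (limma, Benjamini-Hochberg adjusted p under 0.05), 1742 higher and 1458 lower in TRM, and 919 and 563 of these by at least 2-fold. The 4 libraries of each group did not overlap for 27.4% of the genes, where chance gives 2.86%. Rescaling each library to the same total moved the median of all genes to -0.15 on the log2 scale and the counts to 1303 higher and 2263 lower (36.5% higher in place of 54.4%). Quantile normalization gave 1496 and 1927 (43.7%). Without TRM 2-1 and TRM 2-2, left out after the data were seen, 1140 genes were higher and 1169 lower.

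**Figure D4:**
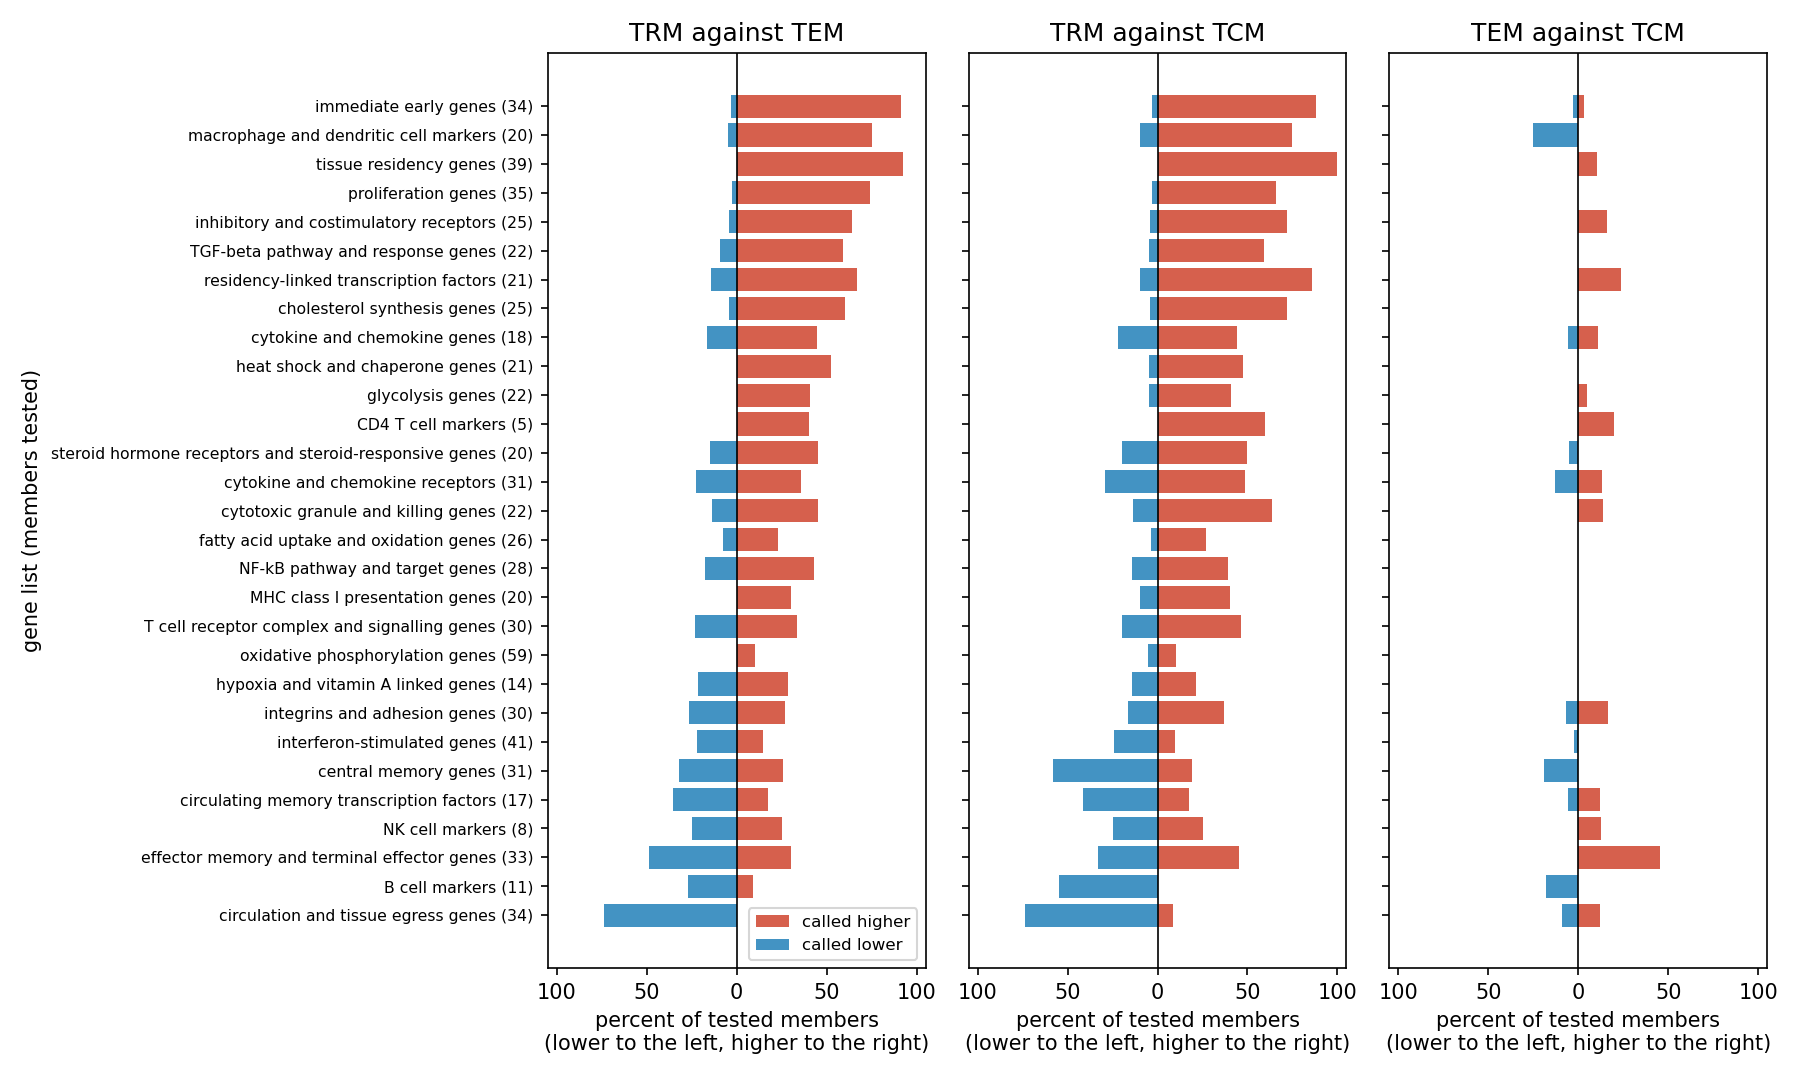
Percent of the tested members of each fixed gene list that were called in the 3 comparisons, higher to the right of 0 and lower to the left, with the number tested in brackets. In TRM against TEM, 36 of 39 tissue residency genes were higher and 25 of 34 circulation and tissue egress genes were lower.

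The second comparison set TRM against central memory cells. Il7r, the receptor chain for the survival cytokine IL-7, stood at 602 ± 130.4 in TRM and 3372 ± 299 in TCM (log2 fold change -2.50 ± 0.14, limma adjusted p = 4.03e-11), and Ccr7, the chemokine receptor of lymph node entry, at 568 ± 323 and 1180.5 ± 112. The TRM mean of Ccr7 was raised by TRM 2-2, at 1047 against 339 to 452 in the other TRM libraries. Tcf7 (chromosome 11, 52252371 to 52283014), whose product TCF-1 supports long-lived memory, stood at 701 ± 122 and 2242 ± 152 (log2 fold change -1.69 ± 0.11, adjusted p = 8.94e-10). Gzmb (chromosome 14, 56258838 to 56262260) went the other way, from 569 ± 109 in TCM to 7162 ± 1174 in TRM (log2 fold change 3.65 ± 0.16, adjusted p = 2.17e-12). Itgae and Cd69 were higher in TRM by log2 fold changes of 6.12 and 2.82, and S1pr1 fell by 2.44.

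All 39 tissue residency genes rose in TRM against TCM, over all genes and adjusted over the list alone (camera adjusted p = 1.35e-39, and adjusted p = 1.10e-04 with an estimated correlation). Of 34 circulation and tissue egress genes 25 fell and 3 rose, 26 and 3 adjusted over the list alone (camera adjusted p = 2.90e-16, and adjusted p = 5.60e-04 with an estimated correlation). The 3 that rose were Dok2, Itgal and Itgb7, of which the last 2 encode integrin chains. Among 21 residency-linked transcription factors 18 rose, including Zfp683 (2.18) and Prdm1, which encodes Blimp-1 (1.61), and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 1.20e-12, and adjusted p = 0.00683 with an estimated correlation). Of 17 circulating memory transcription factors 7 fell and 3 rose, 7 and 4 adjusted over the list alone (camera adjusted p = 0.00786, adjusted p = 0.0546 with an estimated correlation, and 0.917 without the genes of other lists). Of 31 central memory genes 18 fell and 6 rose, 18 and 7 adjusted over the list alone (camera adjusted p = 5.80e-05, and adjusted p = 0.222 with an estimated correlation). Xcl1, which encodes a T cell chemokine that attracts cross-presenting dendritic cells, was among those that rose (647 ± 63.4 in TRM, 31.2 ± 8.11 in TCM), and Eomes among those that fell (58.9 ± 12.3 and 145 ± 17.3). Of 22 TGF-beta genes 13 rose and 1 fell, 16 and 1 adjusted over the list alone (camera adjusted p = 8.69e-06, and adjusted p = 0.00485 with an estimated correlation).

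Of 25 inhibitory and costimulatory receptors 18 rose and 1 fell in TRM against TCM, the same numbers adjusted over the list alone (camera adjusted p = 1.50e-11, and adjusted p = 5.60e-04 with an estimated correlation), with Pdcd1 at 1419 ± 295 against 69.9 ± 16.2 (log2 fold change 4.31 ± 0.18, limma adjusted p = 7.08e-13). Of 34 immediate early genes 30 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 4.24e-29, and adjusted p = 5.76e-04 with an estimated correlation). Fos stood at 12.6 ± 9.49 in TCM. Of 25 cholesterol synthesis genes 18 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 3.51e-05, and adjusted p = 0.0270 with an estimated correlation), among them Insig1 (2.66). Of 21 heat shock genes 10 rose and 1 fell, 11 and 1 adjusted over the list alone (camera adjusted p = 0.00192, and adjusted p = 0.0673 with an estimated correlation). Of 22 cytotoxic genes 14 rose and 3 fell, 15 and 4 adjusted over the list alone (camera adjusted p = 1.63e-05, and adjusted p = 0.0658 with an estimated correlation). Gzma was among them (349 ± 173 in TRM, 108 ± 158 in TCM, adjusted p = 0.0130), a call lost without TCM 2-2 (adjusted p = 0.0552). Of 18 cytokine and chemokine genes 8 rose and 4 fell, 9 and 4 adjusted over the list alone (camera adjusted p = 0.00402, and adjusted p = 0.0687 with an estimated correlation), with Ifng at 31.9 ± 2.21 in TCM. Of 35 proliferation genes 23 rose and 1 fell, 25 and 1 adjusted over the list alone (camera adjusted p = 9.59e-09, and adjusted p = 0.102 with an estimated correlation), with Mki67, which marks cycling cells, at 151 ± 29.7 and 14.1 ± 12.9.

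The remaining lists called in TRM against TCM each lost the call with an estimated correlation. Of 28 NF-kB genes 11 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.111 with an estimated correlation, and 0.145 without the genes of other lists). Of 22 glycolysis genes 9 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00602, and adjusted p = 0.217 with an estimated correlation). Of 20 steroid-linked genes 10 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0193, adjusted p = 0.0658 with an estimated correlation, and 0.324 without the genes of other lists). Of 31 cytokine and chemokine receptors 15 rose and 9 fell, 16 and 9 adjusted over the list alone (camera adjusted p = 0.0333, and adjusted p = 0.0902 with an estimated correlation), a call also lost without TRM 2-2 (adjusted p = 0.0587), without TCM 1-1 (0.0552) and after quantile normalization (0.0501). Of 30 T cell receptor and signalling genes 14 rose and 6 fell, 15 and 6 adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.218 with an estimated correlation, and 0.356 after quantile normalization). Cd8a and Cd3g rose by 0.80 and 0.80. Of 20 macrophage and dendritic cell markers 15 rose and 2 fell, 18 and 2 adjusted over the list alone (camera adjusted p = 2.50e-04, and adjusted p = 0.273 with an estimated correlation). That call was also lost without TRM 2-1 and TRM 2-2 (camera adjusted p = 0.0619). Of 11 B cell markers 6 fell and 0 rose, also 6 adjusted over the list alone (camera adjusted p = 0.00191, and adjusted p = 0.149 with an estimated correlation), with Cd79a, a chain of the B cell receptor, at 1.41 ± 2.01 in TRM and 36.7 ± 8.76 in TCM. Of 5 CD4 T cell markers 3 rose, also 3 adjusted over the list alone (camera adjusted p = 0.00188, and adjusted p = 0.0658 with an estimated correlation).

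Between TRM and TCM 3671 genes differed, 2003 higher and 1668 lower in TRM, and 1057 and 639 of these by at least 2-fold. The groups did not overlap for 28.5% of the genes, where chance gives 2.86%. Rescaling to the same total gave 1602 higher and 2240 lower (41.7% higher in place of 54.6%, with the median of all genes at -0.11). Quantile normalization gave 1661 and 2152 (43.6%).

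The genes that set TRM apart from one spleen group largely set it apart from the other. Against both TEM and TCM 1395 genes were higher in TRM and 1095 lower, and 0 were called in opposite directions. Rescaling to the same total gave 1079 higher and 1631 lower, and quantile normalization gave 1184 and 1473. The shared genes included Vps37b, a vesicle sorting gene (2452 ± 237 in TRM, 154 ± 15.7 in TEM, 172 ± 23.4 in TCM), Cxcr4, the CXCL12 receptor (611 ± 43.4, 28.5 ± 8.32 and 51.6 ± 6.02), and, among those lower in TRM, Cmah, a sialic acid hydroxylase (159 ± 15.5, 683 ± 33.8 and 814 ± 103). Both comparisons use the same TRM libraries. Independent lists of these lengths would share 287 higher and 200 lower genes (n1 × n2 / N). With 2 TRM libraries set against TEM and the other 2 against TCM, the 6 splits gave 859 to 903 higher and 551 to 572 lower genes. Over genes, which are not independent replicates, the 2 sets of fold changes had a correlation of 0.898 against 0.500 with simulated unchanged groups and 0.770 to 0.789 with the TRM libraries split. Their covariance was 0.749 against 0.0516 simulated, a difference of 0.698.

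The third comparison set the spleen groups against each other. Ccr7 stood at 374 ± 122 in TEM and 1180.5 ± 112 in TCM (log2 fold change -1.71 ± 0.25, limma adjusted p = 0.00212), a call lost with a variance prior that has no trend (adjusted p = 0.0753) and on set 2 alone (0.0821). Gzmb was higher in TEM (1842 ± 497 against 569 ± 109, log2 fold change 1.67 ± 0.16, adjusted p = 1.51e-05). So were Cx3cr1 (chromosome 9, 119901616 to 120069879; 1991 ± 1242 against 382 ± 219), Klrg1 (836 ± 410.5 against 206 ± 135), Zeb2 (710 ± 439 against 182 ± 82.3) and Klrb1c, which encodes NK1.1 (708 ± 288 against 135 ± 33.3). Bhlhe40, a transcription factor of effector and resident cells (chromosome 6, 108660629 to 108666925), Lgals3, which encodes galectin-3, and Itga1 were higher in TEM by 1.70, 2.00 and 1.33 on the log2 scale. In TRM, Bhlhe40 stood at 1926 ± 171, above 466 ± 139.6 in TEM and 137 ± 8.997 in TCM.

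Of 33 effector memory and terminal effector genes 15 rose in TEM against TCM and 0 fell, 25 and 0 adjusted over the list alone, with a median log2 fold change of 0.67 (camera adjusted p = 2.58e-34, and adjusted p = 0.0118 with an estimated correlation). Of 31 central memory genes 6 fell and 0 rose, 20 and 1 adjusted over the list alone (camera adjusted p = 1.38e-19, and adjusted p = 0.0273 with an estimated correlation). They included Dapl1, a gene of naive and memory-precursor cells (7.78 ± 7.60 in TEM, 65.97 ± 17.8 in TCM). Of 39 tissue residency genes 4 rose and 0 fell, 10 and 0 adjusted over the list alone (camera adjusted p = 1.36e-05, and adjusted p = 0.0243 with an estimated correlation). These 4 were Cxcr6, Itga1, Zfp683 and P2rx7, a receptor for extracellular ATP (91.2 ± 21.3 in TEM, 14.7 ± 11.4 in TCM, 816 ± 139 in TRM). Of 21 residency-linked transcription factors 5 rose and 0 fell, 9 and 0 adjusted over the list alone (camera adjusted p = 5.89e-11, and adjusted p = 0.0107 with an estimated correlation), with Bhlhe40, Rora (0.90) and Id2 (0.58) among them. Of 30 integrins and adhesion genes 5 rose and 2 fell, 10 and 2 adjusted over the list alone (camera adjusted p = 7.37e-04, and adjusted p = 0.0243 with an estimated correlation), and without the genes of other lists the adjusted p was 0.556. Of 22 cytotoxic genes 3 rose and 0 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 7.28e-06, adjusted p = 0.0619 with an estimated correlation, and 0.324 without the genes of other lists).

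Of 25 inhibitory and costimulatory receptors 4 rose in TEM against TCM and 0 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.0171, adjusted p = 0.0658 with an estimated correlation, and 0.0643 without the genes of other lists), a call lost without TEM 2-1 (adjusted p = 0.0865). Of 30 T cell receptor and signalling genes 0 passed the test in either direction (camera adjusted p = 0.0316, and adjusted p = 0.222 with an estimated correlation), a call lost without TCM 2-1 (0.117), TCM 2-2 (0.0656), TEM 1-2 (0.0795) or TEM 2-1 (0.0865). Of 20 macrophage and dendritic cell markers 5 fell and 0 rose, 6 and 1 adjusted over the list alone (camera adjusted p = 8.65e-05, and adjusted p = 0.241 with an estimated correlation), a call lost without TCM 1-1 (adjusted p = 0.157). H2-Eb1 stood at 13.6 ± 3.68 in TEM and 70.7 ± 30.2 in TCM. Of 11 B cell markers 2 fell and 0 rose, also 2 adjusted over the list alone (camera adjusted p = 6.17e-05, and adjusted p = 0.0772 with an estimated correlation). These were Cd79a and Ms4a1, which encodes CD20 (3.91 ± 2.74 and 38.7 ± 17.9). The calls of both rested on single libraries: Ms4a1 was lost without TEM 1-1 (adjusted p = 0.0534), and Cd79a without TRM 2-2, any TCM library or TEM 1-1, 1-2 or 2-1 (adjusted p from 0.0509 to 0.149).

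Between TEM and TCM 112 genes differed, 75 higher and 37 lower in TEM, out of 1369 at an unadjusted p under 0.05. The groups did not overlap for 6.68% of the genes, where chance gives 2.86%. The count changed by more than 1.5 times with single libraries: 273 genes were called without TCM 1-1, 56 without TCM 1-2, 62 without TCM 2-1, 67 without TCM 2-2, 49 without TEM 1-1 and 42 without TEM 1-2. Without TEM 2-1 the genes lower in TEM came to 67. With a variance prior that has no trend 23 were called, 17 higher and 6 lower. Of the genes named above, that prior ended the calls of Cx3cr1 (adjusted p = 0.0926), Klrg1 (0.0753), Zeb2 (0.137), Klrb1c (0.0753), Dapl1 (0.0719), Id2 (0.122), Cxcr6 (0.142), H2-Eb1 (0.0998) and Cd79a (0.0753). Gzmb, Bhlhe40, Lgals3 and Itga1 kept their calls under each of the 32 alternatives run.

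In the genes that differ between the spleen groups, TRM resembled neither throughout. Of the 75 genes higher in TEM, 33 were called higher in TRM than in both spleen groups and 6 lower than in both, while 55 were called higher than in TCM and 19 lower than in TEM. Of the 37 genes higher in TCM, 23 were called lower in TRM than in TCM and 10 higher than in both groups. Gzmb and P2rx7 were among the genes in which TRM exceeded both, and Klrg1 and Zeb2 among those in which TRM stood below TEM and near TCM (129.8 ± 18.4 and 206 ± 135 for Klrg1, 181 ± 30.4 and 182 ± 82.3 for Zeb2). On a scale from 0 at the TEM mean to 1 at the TCM mean the median position of the 4 TRM libraries was -0.0802 ± 0.0422 (SD, n = 4), at -0.256 ± 0.0364 in genes higher in TEM and 0.156 ± 0.124 in genes higher in TCM. This position had no test of its own, and its genes were called on the libraries that set the scale. It was -0.587 with genes called on set 1 and measured on set 2, and 0.00319 the other way. It moved to -0.134 without TRM 2-2, to -0.201, -0.268 and -0.221 without TCM 1-2, TCM 2-1 and TCM 2-2, and to 0.113 and 0.0901 without TEM 2-1 and TEM 2-2.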

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

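All tests of explanations and of other splits in this part were chosen after the results they address were seen, except the comparison of immediate early genes with macrophage transcripts, and the criterion for exchanged spleen libraries was rewritten after its first result was seen. Of 336 groups of 4 libraries tested, 31 held a library far from the other 3. Chance gives about 1 in 20 for independent values with a normal distribution. Among the 31 were 9 of 54 groups of library measures and 22 of 282 groups of gene levels. The values were tested without a log transform and some measures share genes, so that rate is a rough guide. A single flagged gene can thus be due to chance.

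Library TCM 1-1 stood out for the share of reads of Gm10800 (6.51% against 1.32% to 2.09%), a satellite-like gene model, for mitochondrial reads (5.80% against 1.74% to 2.11%) and for the sum of C1q, Lyz2 and Csf1r transcripts (358.7 against 2.28 to 20.8). In the same library Klrg1 (408.2 against 130.9 to 149.1), Ccl3 (52.9 against 29.5 to 30.7), Gzma (343.8 against 12.998 to 39.7) and Apoe (193.2 against 38.3 to 59.8) stood above the other TCM libraries. Its smaller differences in Cd3g (2955.0 against 2607 to 2664) and Icos (253.0 against 281.6 to 285.0) stood out because the other 3 libraries lay close together. TCM 1-2 stood out for Tcf7 (2469, high) and Hspa5 (1344, low), and TCM 2-2 for Prdm1 (48.5, low) and Nlrc5 (1509, high).

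TRM 2-1 stood out for prostate epithelium markers (1644 against 389.9 to 441.8), seminal vesicle markers (156.1 against 2.85 to 18.9) and Tgm4 (509.7 against 18.5 to 25.7). TRM 2-2 stood out for B cell markers (19709 against 320.2 to 1356), for Ighm, Igkc and Jchain together (19598), and for Klrb1c (106.8), Ccr7 (1047) and Rarg (41.9), all high. TRM 1-2 was low in Klrg1 (102.5), Nsg2 (14.2) and Ifi47 (909.3). TEM 1-1 stood out for NK cell markers (2584 against 1847 to 1890.1), Itgae (73.7), Klrb1c (1137) and Apoe (34.5), all high, and Socs3 (46.0, low). TEM 1-2 stood out for red blood cell and platelet markers (48.6 against 14.0 to 15.3) and TEM 2-2 for Cyp51 (110.8, high).

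The first pattern is that of macrophage and MHC class II transcripts. Over the 4 TRM libraries the ratio of MHC class II to C1q, Lyz2 and Csf1r transcripts varied 1.417-fold while the MHC class II sum varied 4.27-fold, which is consistent with macrophage RNA in the prostate sort as a candidate source, although the gate on P14 cells would remove macrophages. B cell transcripts came to at most 6.07% of the MHC class II sum in a TRM library. They came to 41.9% to 95.9% in TCM and 88.6% to 310% in TEM. B cell RNA at the ratio seen in TCM is thus argued against as the source in TRM. No library of B cells was measured, so B cell RNA at another ratio stays open. For the higher MHC class II sum of TCM against TEM, macrophage RNA was taken at the median ratio of the prostate TRM libraries. At that ratio it is argued against in 3 of the 4 TCM libraries, in which it would account for 1.54%, 11.5% and 15.0%. It stays open in TCM 1-1. The ratio in spleen macrophages was not measured. B cell RNA was not tested as a source of this difference. The sum of B cell transcripts lay between 162 and 329 in TCM and between 96.7 and 146 in TEM. A difference between the tissues themselves was not tested.

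The second pattern is the rise of immediate early genes in TRM. Macrophage RNA as the source is argued against: between set 2 and set 1 of the TRM libraries the 31 called genes had a median ratio of 1.01 (quartiles 0.878 and 1.13) while the macrophage transcripts had 3.57. An effect of the digestion at 37 °C cannot be told apart from a state of the cells in the tissue, since the prostate alone was digested, and 11 heat shock genes were higher in TRM as well. Both may contribute.

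The third pattern is the low number of genes called between TEM and TCM. An exchange of TCM 1-1 with TEM 1-1 is argued against, since on an axis from TEM (0) to TCM (1) TEM 1-1 lay at -0.41 (upper quartile -0.06), away from TCM, while TCM 1-1 lay at 0.46. The first criterion asked only whether TCM 1-1 lay over 0.5, which it did not. TEM cells mixed into TCM 1-1 cannot be told apart from other causes: TCM 1-1 lay on the TEM side of the other TCM libraries in 72.1% of 68 genes, where chance gives 25%, with 77.4% of 53 genes higher in TEM and 53.3% of 15 lower in TEM, but the genes were picked on those other libraries. Spread added by TCM 1-1 is consistent with the 273 genes called without it against 112 with it.

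Splits of the libraries were tried for each count, 35 for 2 groups and 100 for the calls shared by both TRM comparisons, the real one included. The real split called the most genes in TRM against TEM (3200, highest other split 1) and in TRM against TCM (3671, highest other 0). It also did so in TEM against TCM (112, highest other 24). The same held for the 1395 genes higher (highest other 0) and 1095 lower (highest other 1) in TRM than in both. For lists with the estimated correlation the real split was highest in TRM against TEM (8, highest other 0) and TRM against TCM (7, highest other 0). In TEM against TCM it was highest as well (5, highest other 1). Other splits mix the groups compared, so real differences widen their spread and low counts were likely in advance. Which libraries share mice is not known, so these counts cannot exclude chance differences between animals. With the preset correlation the real split was highest in TRM against TEM (18, highest other 17) and TRM against TCM (21, highest other 20). Another split called nearly as many lists in each, so these counts do not exclude chance. Nor do those of TEM against TCM, where 4 of the 35 splits, the real one included, gave at least the real 10 and the highest other gave 10. The p-values with the preset correlation are therefore to be read beside those with an estimated one.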

How the results depend on the processing

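The alternatives voom, log2 with no further pseudocount, 1 set only and fits without 2 libraries were chosen after the data were seen. Of 320 comparisons of named genes, 251 passed the threshold, and 160 of these kept direction and call under each of the 32 alternatives in which the gene passed the filter. Counted by comparison and alternative, over 10132 cases, a call was lost in 379, gained in 32, and turned direction in 0. A turn was counted only where the main or the alternative fit made a call. The cause was not tested for any change below unless given. The planned edgeR and DESeq2 tests were not run: the unit of the deposited values was recorded as a normalised signal, and of the tests for counts only voom was run on the reads recovered from it.

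Counts moved by more than 1.5 times as follows. In TEM against TCM, with 75 genes higher and 37 lower in TEM, no filter gave 68 lower, a fit of these 2 groups alone 40 higher and 22 lower, averaged sets 44 and 15, array weights 162 and 102, no variance trend 17 and 6, and voom 58 lower. A block for the 4 replicate numbers gave 164 genes, 67 of them lower, and a block for the 2 set numbers 173, 76 of them lower. The numbers were not taken to pair the libraries: over the 12 same-number pairs residual correlations ran from -0.0370 to 0.103, with 1 over 0.1, and the correlation within sets was -0.0129. Between TEM and TCM, however, each of the 4 same-number pairs (0.103, 0.0376, 0.0542 and 0.0954) was the best match of its number, so whether spleen libraries with the same number share mice stays open. With the replicate block the cytokine and chemokine receptor list in TRM against TCM had an adjusted p of 0.0561, and no other called list lost its call. In TRM against TEM, rescaling to the same total gave 2263 lower, and leaving out TRM 2-1 and TRM 2-2 gave 1140 higher.

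A required change of 2-fold left 919 higher and 563 lower in TRM than TEM, 1057 and 639 against TCM, 737 and 413 against both, and 45 and 21 in TEM against TCM, fewer by construction. With fewer libraries, set 1 alone gave 806 and 527, 892 and 562, 598 and 345, and 15 and 6 in the same order, and set 2 alone gave 1147 and 791, 1047 lower than TCM, 914 and 616 against both, and 24 and 5.

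Leaving out 1 library at a time gave 1370 to 1944 genes higher and 1149 to 1646 lower in TRM than TEM, 1630 to 2097 and 1326 to 1717 against TCM, 1089 to 1500 and 920 to 1162 against both, and 32 to 196 higher and 10 to 77 lower in TEM than TCM. Without TCM 1-1 the last pair was 196 and 77, and without TCM 1-2 it was 45 and 11. It was 46 and 16 without TCM 2-1, 55 and 12 without TCM 2-2, 34 and 15 without TEM 1-1, and 32 and 10 without TEM 1-2. Without TEM 2-1 67 were lower. Of the 112 genes 104 were also called without TCM 1-1 and 19 of the 23 called with no variance trend were among them.

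Of 87 list tests 49 were called, 48 to 57 without single libraries, and 20 with an estimated correlation. Without the genes of other lists, the effector memory and terminal effector genes turned from lower to higher in TRM than TEM (adjusted p = 0.328). The position of TRM between TEM and TCM, -0.0802, moved to -0.587 and 0.00319 when genes were called on 1 set and measured on the other, -0.130 with quantile normalization, -0.251 without TCM 1-1 and TEM 1-1, and -0.241 without TRM 2-1 and TRM 2-2. It ran from -0.268 without TCM 2-1 to 0.113 without TEM 2-1, with -0.134 without TRM 2-2, -0.201 without TCM 1-2, -0.221 without TCM 2-2 and 0.0901 without TEM 2-2. At this depth 1 read is worth up to 1.423 normalised counts. That limits what can be said of genes near the filter of 10.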

Other observations

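Of the tests in this part, that of Xist and Y-linked reads was chosen after the result was seen. Lists that were not called complete the picture of the prostate cells. Of 59 tested oxidative phosphorylation genes 6 rose and 0 fell in TRM against TEM, 5 and 0 adjusted over the list alone (camera adjusted p = 0.440). Of these 6 rose and 3 fell against TCM, 6 and 2 over the list alone (camera adjusted p = 0.290). Of 41 interferon-stimulated genes 6 rose and 9 fell against TEM, 7 and 9 over the list alone (camera adjusted p = 0.539). Of these 4 rose and 10 fell against TCM, 5 and 10 over the list alone (camera adjusted p = 0.134). Of 20 MHC class I presentation genes 6 rose and 0 fell against TEM, also 6 over the list alone (camera adjusted p = 0.0699). Of these 8 rose and 2 fell against TCM, 10 and 3 over the list alone (camera adjusted p = 0.0790). Of 26 fatty acid uptake and oxidation genes 6 rose and 2 fell against TEM (camera adjusted p = 0.0739) and 7 rose and 1 fell against TCM (camera adjusted p = 0.0934), the same numbers over the list alone. Of 14 hypoxia and vitamin A linked genes 4 rose and 3 fell against TEM, 4 and 4 over the list alone (camera adjusted p = 0.953). Of these 3 rose and 2 fell against TCM, the same over the list alone (camera adjusted p = 0.634).

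Against TEM, 8 of 31 central memory genes rose and 10 fell, 9 and 10 over the list alone (camera adjusted p = 0.446), and 11 of 31 cytokine and chemokine receptors rose and 7 fell, the same over the list alone (camera adjusted p = 0.0934). Likewise 8 of 30 integrins and adhesion genes rose and 8 fell, 9 and 9 over the list alone (camera adjusted p = 0.491), and 10 of 30 T cell receptor and signalling genes rose and 7 fell, the same over the list alone (camera adjusted p = 0.0967). Against TCM, 15 of 33 effector memory and terminal effector genes rose and 11 fell, 16 and 13 over the list alone (camera adjusted p = 0.132). Of the other lists, 11 of 30 integrins and adhesion genes rose and 5 fell, 12 and 7 over the list alone (camera adjusted p = 0.0578), and 2 of 8 NK cell markers rose and 2 fell, 3 and 3 over the list alone (camera adjusted p = 0.903). Between TEM and TCM, 1 of 34 immediate early genes rose and 1 fell, 3 and 3 over the list alone (camera adjusted p = 0.424).

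Xist, the transcript of the inactive X chromosome, stood between 1807 and 4576 normalised counts in the 12 libraries, although the prostate is an organ of male mice. Y-linked genes had 1 to 14 reads in a library against 796 to 1361 for their homologues on the X chromosome, at most 1.28%. A hypothesis is that the P14 cells came from female donors, with which this value is consistent. The labels give no sex, and the share of reads from host cells was not tested.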
